A study of Haloxylon ammodendron with 6 samples.

How the data were processed

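RNA was sequenced from whole seedlings of the desert shrub Haloxylon ammodendron. Per the labels' protocols, seedlings were raised on filter paper with half-strength Hoagland nutrient solution at 22 °C under 16 h of light and 8 h of darkness. After 3 days, drought stress was imposed with 5% PEG 6000, a polymer that lowers the water potential of the medium, for 7 days, and the labels give an age of 10 days for both groups. The 6 libraries formed 2 groups, control and PEG, with 3 libraries each, which the labels' protocols call biological replicates. Per the labels' protocols, total RNA was extracted with TRIZOL and sequenced as paired-end reads on an Illumina platform.

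The authors deposited 12 tables, 1 of coding and 1 of noncoding transcripts per library. Each holds raw counts per transcript, whole numbers that were not normalised, per the file headers and the values. The coding tables list 36099 transcripts and the noncoding ones list 78705, with the same identifiers in every library. Per the file headers, the transcripts belong to a merged collection that was divided into a coding and a noncoding set. The aligner, the counting tool and the assembler are not given in the sources used here. The submitters' processing notes name TAIR10, an Arabidopsis genome build, without stating its role. The identifiers are serial numbers, and the files do not pair them with gene names, sequences, lengths or positions. No reference genome was used here. The file headers end in a short code that includes the word mhits, and no source used here explains it. Whether reads shared between similar transcripts were split, discarded or counted more than once is therefore unknown here, and counts of near-identical transcripts are uncertain. Library type with respect to strand is likewise not given.

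Coding totals ran from 33072346 (control 2) to 41586155 (PEG 1) counts per library, and noncoding totals from 3154455 (control 2) to 4098635 (control 3). The median tested coding transcript with a mean log2 CPM above 5 had 2820 counts per library, and one below 1 had 26. The libraries of a group were compared before averaging. Chi-square per degree of freedom was at least 24.5 for coding and at least 4.12 for noncoding counts over the within-group pairs. No pair agreed within counting error, the only error this comparison covers, so no library was treated as a second deposit of another. Each was counted as a separate sample, as the labels have it.

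Coding and noncoding tables were analysed separately with edgeR 4.0.16 in R 4.3.3. Transcripts passing filterByExpr were scaled by TMM factors and tested with the robust quasi-likelihood test (glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all tested transcripts of the class. The threshold was an adjusted p of 0.05. Changes beyond 2-fold were tested with glmTreat against a log2 fold change of 1. The filter kept 28790 coding transcripts holding 99.9% of coding counts and 31811 noncoding transcripts holding 94.4% of noncoding counts. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the quasi-likelihood F. Shares of counts were compared by exact two-sided permutation tests, which cannot give a p below 0.1 with 3 against 3 libraries. Principal components were computed on log2 CPM with a prior count of 2.

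The test, the filter, the alternatives and the rule for naming transcripts were set before the data were examined. For identifiers without names, the rule took, per class and direction, the transcript with the largest fold change among those with an adjusted p below 0.05, a mean log2 CPM of at least 3 and no overlap between the groups. It yielded 1 transcript. The transcript with the smallest p per class and direction was added after the values were seen. For the same reason, 19 lists of Arabidopsis stress, photosynthesis, growth and organ marker genes could not be applied, and no set test was run. Counts could not be summed per gene, since the identifiers show no gene.

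The test was checked on simulated counts drawn from the means, library sizes and fitted dispersions of the real libraries, with 200 changed transcripts per class. In the coding simulation, over 28126 tested transcripts, edgeR called 23 of 76 transcripts changed 2-fold, 37 of 55 changed 4-fold and 59 of 69 changed 8-fold, with 10 false calls. In the noncoding simulation, over 29583 tested transcripts, it called 4 of 71, 35 of 60 and 48 of 69, with 5 false calls. On the same simulated counts, 67 of 202 coding calls and 18 of 118 noncoding calls of DESeq2 were false. With no transcript changed, edgeR called 10 coding and 2 noncoding transcripts, and DESeq2 62 and 7. The simulated transcripts were drawn independently of one another. Differences between libraries that many transcripts share, as on the first principal component of the real data, were therefore absent. The recovered numbers show how the tests behave on such counts and do not give their power in the real libraries.

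Alternatives were RLE size factors, library totals alone, both classes in 1 fit, no filter, a filter of 1 CPM in 3 libraries, an adjusted p of 0.01, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. limma 3.58.1 with voom, DESeq2 without its own filter on the transcripts tested by edgeR, a prior without the robust option, an adjusted p of 0.1 and leaving out control 1 together with PEG 3 were added after seeing the data. For a single transcript, the thresholds of 0.01 and 0.1 repeat the values of the main fit, and both DESeq2 runs are close to one another. The 19 alternatives counted per transcript are therefore not independent. The labels number the replicates 1 to 3 in both groups.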

Results

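The transcriptome of Haloxylon ammodendron seedlings was measured by RNA sequencing after 7 days on 5% PEG 6000 and in control seedlings, with 3 libraries per group. The series addresses survival of this desert shrub at the seedling stage, and the comparison asks which coding and noncoding transcripts differ under osmotic stress. Coding counts totalled 35185327, 33072346 and 41283461 in controls 1 to 3, and 41586155, 36325574 and 37068483 in PEG 1 to 3. Noncoding counts totalled 3230575, 3154455 and 4098635 in controls 1 to 3, and 4061716, 3494269 and 3350696 in PEG 1 to 3. Between 33910 and 34299 of the 36099 coding transcripts had at least 1 count in a library. The transcripts carry serial identifiers only, so they are described by class, abundance and size of change, and no gene function is assigned.

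Coding transcripts were compared first. No coding transcript among the 28790 tested passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and the smallest adjusted p was 0.0675. Most fold changes were small. The log2 fold change lay within 1.5-fold of no change for 85.4% of tested coding transcripts and beyond 2-fold for 4.66%, with a median standard error of 0.23. An unadjusted p below 0.001 was reached by 118 coding transcripts, where 28.8 would be expected by chance. Of these, 49 had higher and 69 lower values under PEG, and 86 differed by more than 2-fold. An unadjusted p below 0.05 was reached by 2624, against 1440 expected by chance. All 3 PEG libraries lay on one side of all 3 controls for 15.8% of the tested coding transcripts, where chance gives 10%. When the libraries were regrouped 3 against 3 with both conditions in each group, the highest values were 25 with a p below 0.001, 2344 with a p below 0.05 and 14.2% without overlap. Such groupings keep part of any PEG difference, so these values are no null level.

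The count of coding calls differed between tests. DESeq2, which applies its own filter, gave an adjusted p for 32372 coding transcripts and called 378 of them at an adjusted p below 0.05, with 148 higher and 230 lower under PEG. Run without that filter on the 28790 transcripts tested by edgeR, it called 424, of which 361 were among the 378. The median log2 fold change of its calls was 1.097 for the higher and -1.34 for the lower transcripts. Of the 378, 240 differed by more than 2-fold and 95 by more than 4-fold, and the groups did not overlap for 364. All 118 coding transcripts with an edgeR p below 0.001 were among the 378. Both tests used the same counts, and calls chosen for a group difference tend to keep the groups apart. Neither the 364 nor the 118 is therefore separate support for the calls. limma voom called 0. Without control 3, edgeR called 32 coding transcripts, 27 of them lower under PEG, without control 1 it called 2, and with both classes in 1 fit it called 1. With the replicate number as a block, edgeR called 342, of which 167 were higher and 175 lower under PEG. Whether the numbers pair the libraries is not given in the sources used here. The common biological coefficient of variation was 0.252 for coding transcripts.

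**Figure D1:**
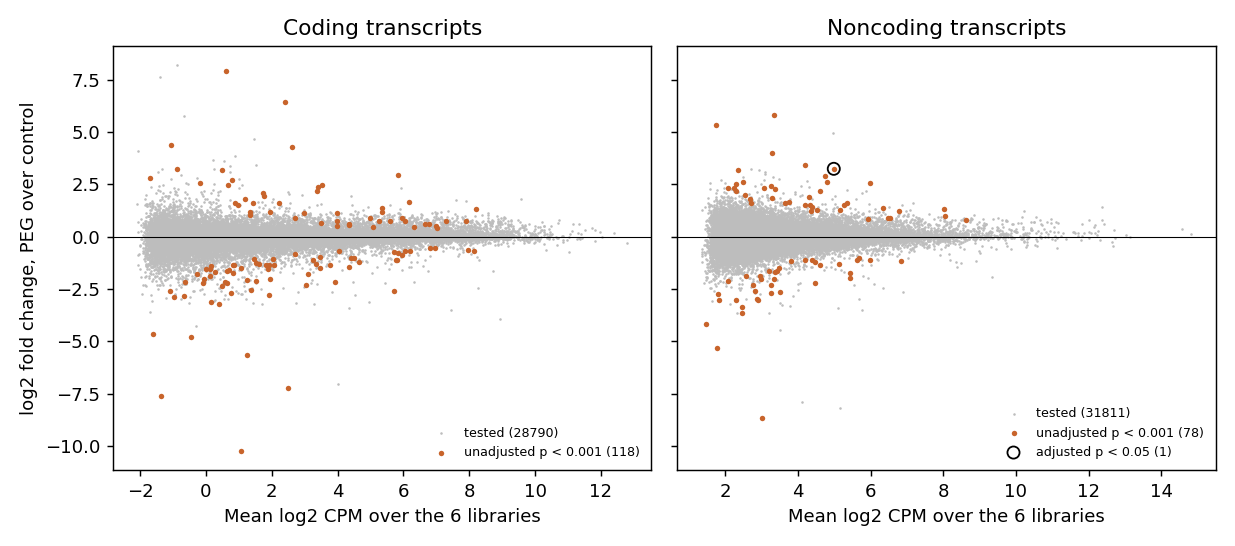
Log2 fold change of PEG over control (vertical axis) against mean log2 CPM over the 6 libraries (horizontal axis) for 28790 coding (left) and 31811 noncoding (right) transcripts. Orange points mark the 118 coding and 78 noncoding transcripts with an unadjusted p below 0.001, and the open circle marks the 1 noncoding transcript with an adjusted p below 0.05.

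The coding transcript with the smallest p was Rep36835, chosen after its values were seen. It stood at 11.1 ± 4.37 CPM in controls (SD, n = 3) and 0.0680 ± 0.0461 CPM under PEG (SD, n = 3), from 1237 control counts and 8 PEG counts. Its log2 fold change was -7.23 with a standard error of 0.50 (edgeR adjusted p = 0.0675). The adjusted p ranged from 6.2e-27 with DESeq2 on the transcripts tested by edgeR to 0.281 without control 2 over 19 alternatives, of which 6 passed the threshold. Among coding transcripts with higher values under PEG, the smallest p belonged to Rep67417, also chosen after its values were seen. This abundant transcript stood at 169.5 ± 15.4 CPM in controls (SD, n = 3) and 418.9 ± 56.9 CPM under PEG (SD, n = 3), a log2 fold change of 1.305 with a standard error of 0.13 (edgeR adjusted p = 0.0924). Its adjusted p ranged from 2.53e-13 with DESeq2 to 0.281 without control 2. All 3 PEG values lay on one side of all 3 controls for both transcripts.

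Among noncoding transcripts, 1 of the 31811 tested rose and none fell at an adjusted p below 0.05. The transcript that rose, Rep64757, went from 5.90 ± 1.60 CPM in controls (SD, n = 3) to 56.35 ± 15.01 CPM under PEG (SD, n = 3). The increase was 9.51-fold, a log2 fold change of 3.25 with a standard error of 0.29 (edgeR adjusted p = 0.0122). Counts were 14, 23 and 23 in controls 1 to 3 and 157, 181 and 212 in PEG 1 to 3. Over 19 alternatives its log2 fold change stayed between 2.86 and 3.45, and its adjusted p ranged from 2.68e-14 to 0.0953. The call was lost without PEG 2 (adjusted p = 0.0838), with limma voom (adjusted p = 0.0953) and with both classes in 1 fit (adjusted p = 0.0586), and it did not pass the stricter threshold of 0.01. In simulated libraries without any change edgeR called 2 noncoding transcripts, and groupings that mixed the conditions gave up to 2. A count of 1 call therefore does not tell a response to PEG from a false call.

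Noncoding transcripts had lower counts than coding ones, and their fold changes were more scattered. The log2 fold change lay within 1.5-fold of no change for 78.4% of tested noncoding transcripts, with a median standard error of 0.38. An unadjusted p below 0.001 was reached by 78 noncoding transcripts, 41 higher and 37 lower under PEG, against 31.8 expected by chance, and 73 of them differed by more than 2-fold. An unadjusted p below 0.05 was reached by 2181, against 1591 expected by chance. The groups did not overlap for 13.4% of tested noncoding transcripts, where chance gives 10%. Among the groupings that mixed the conditions, the highest values were 62 with a p below 0.001, 2452 with a p below 0.05, which exceeds the 2181, and 13.2% without overlap. DESeq2 called 61 noncoding transcripts, 35 higher and 26 lower under PEG, and 60 of these differed by more than 2-fold. The highest grouping that mixed the conditions gave 66 DESeq2 calls. Of the 78 noncoding transcripts with an edgeR p below 0.001, 38 were among the 61. Without a filter edgeR called 16 noncoding transcripts, and with a filter of 1 CPM in 3 libraries it called 5. With the replicate number as a block it called 133, of which 93 were higher and 40 lower under PEG. It called 26 without control 3, and between 0 and 3 when any other library was left out: 2 without control 1, control 2 or PEG 3, 3 without PEG 1 and 0 without PEG 2.

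The noncoding transcript with the smallest p among those lower under PEG was Rep35245, chosen after its values were seen. It stood at 35.7 ± 10.1 CPM in controls (SD, n = 3) and 7.65 ± 1.87 CPM under PEG (SD, n = 3), a log2 fold change of -2.21 with a standard error of 0.30 (edgeR adjusted p = 0.114). Over 19 alternatives the adjusted p ranged from 2.65e-05 with DESeq2 on the transcripts tested by edgeR to 0.43 with limma voom, and 5 passed the threshold.

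**Figure D2:**
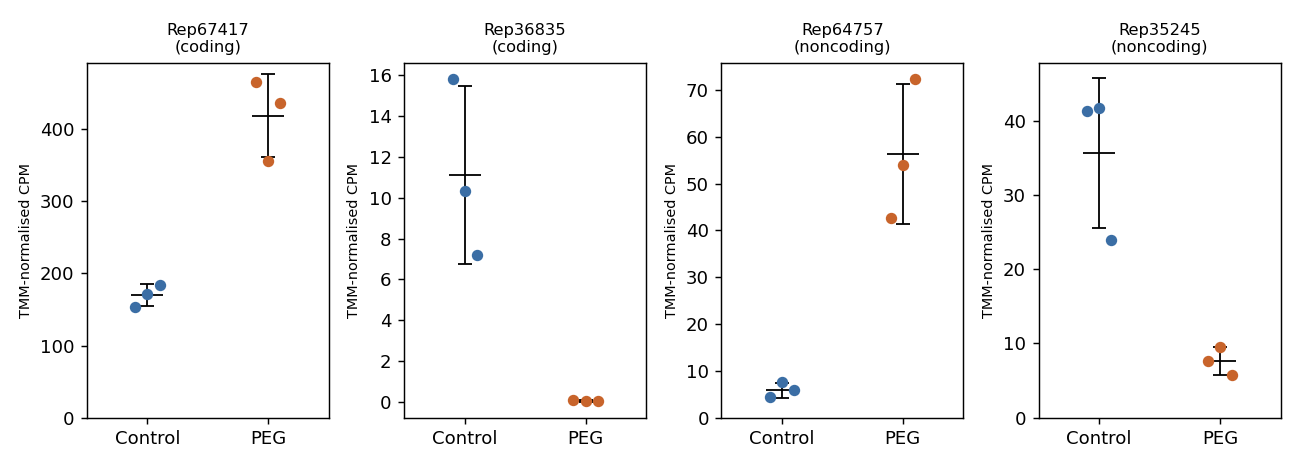
TMM-normalised CPM (vertical axes, each including 0) per library for 4 transcripts in the 3 control and 3 PEG libraries, with dots for libraries and black lines for the mean ± SD. Only Rep64757 passed an adjusted p of 0.05, and for each of the 4 transcripts all PEG values lie on one side of all control values.

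Changes beyond 2-fold were tested directly. Neither class had a transcript whose change exceeded 2-fold at an adjusted p of 0.05 (edgeR glmTreat). The smallest adjusted p was 0.0834 for coding and 0.0627 for noncoding transcripts, and 296 coding and 260 noncoding transcripts had an unadjusted p below 0.05 in this test. Without control 3 the counts were 16 coding and 18 noncoding transcripts. The noncoding count was 3 without PEG 1, 4 without a filter and 1 with a filter of 1 CPM in 3 libraries. The replicate number as a block gave 3 coding and 8 noncoding transcripts. Transcripts seen in only one group were few. With a minimum of 10 counts in every library of the other group, 2 coding transcripts and 1 noncoding transcript had no count in any PEG library, and 2 coding and 0 noncoding transcripts had none in any control. The totals of 4 coding transcripts and 1 noncoding transcript lay within the range of groupings that mixed the conditions, which gave 0 to 5 coding and 1 to 7 noncoding transcripts.

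The balance between the classes was compared next. Noncoding transcripts took 8.72 ± 0.311% of all counts in controls and 8.65 ± 0.322% under PEG (SD, n = 3 each). The difference of -0.0618 percentage points was smaller than the spread between replicates (exact two-sided permutation p = 0.8, smallest possible 0.1), and its sign turned without control 3 (0.0958) or PEG 3 (0.12). The 100 most abundant coding transcripts held 16.0 ± 0.335% of coding counts in controls and 15.9 ± 0.327% under PEG (SD, n = 3 each, exact two-sided permutation p = 0.9). That difference of -0.0785 percentage points also turned sign without control 1 (0.0903), PEG 2 (0.0092) or PEG 3 (0.0227), and for the 1000 most abundant it was 0.977 (exact permutation p = 0.3). The most abundant coding transcript, Rep81644, stood at 8058 ± 1346 CPM of library totals in controls and 6116 ± 1142 under PEG (SD, n = 3 each, edgeR adjusted p = 0.674). The most abundant noncoding transcript, Rep6772, stood at 27160 ± 826 CPM in controls and 27500 ± 1868 under PEG (SD, n = 3 each, edgeR adjusted p = 0.859), on the scale of noncoding totals.

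The classes were also compared at equal CPM, taken relative to each class's own totals. The share of called transcripts could hardly differ, since 0 coding and 1 noncoding transcript were called. The single noncoding call fell between a log2 CPM of 3 and 5, where it was 0.00815% of the 12267 noncoding transcripts. The share with an unadjusted p below 0.05, where chance gives 5%, was 8.39% for the 10996 coding transcripts below a log2 CPM of 1, where no noncoding transcript was tested. It was 9.23% for coding and 6.65% for noncoding transcripts at a log2 CPM of 1 to 3. The shares were 8.93% and 6.23% at 3 to 5, and 10.5% and 9.42% above 5. Equal CPM rests on fewer counts in the noncoding tables, whose totals are smaller. On 1 common scale for both classes the coding share stayed higher below a log2 CPM of 1 (8.66% against 6.11%) and at 1 to 3 (9.32% against 7.65%). The order turned at high abundance, with 9.07% of coding and 11.5% of noncoding transcripts at 3 to 5, and 10.8% and 16.2% above 5. The noncoding shares there rest on 112 of 977 and 47 of 291 transcripts.

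The libraries were then compared with one another. The correlation of log2 CPM over coding transcripts had a median of 0.971 for the 6 pairs within a group and 0.972 for the 9 pairs between groups. For noncoding transcripts the medians were 0.882 and 0.886. The lowest pair between groups, control 1 with PEG 3, stood at 0.947 for coding and 0.800 for noncoding transcripts, against 0.967 and 0.867 for the lowest pair within a group. The mean within groups exceeded that between groups by 0.00419 for coding and 0.0115 for noncoding transcripts, and the highest regrouping of the libraries 3 against 3 gave 0.00414 and 0.0144 (exact one-sided permutation p = 0.1 and 0.2, smallest possible 0.1). These correlations are across transcripts, which are not independent replicates. The first principal component carried 36.9% of the variance of coding and 35.1% of noncoding transcripts. On it, control 1 and PEG 3 lay at opposite ends and the groups overlapped, since PEG 1 scored below control 3 in both classes (exact two-sided permutation p = 0.2 for coding and 0.3 for noncoding, n = 3 each). The second component carried 19.2% and 18.9%. Its coding scores were -3.92, 45.4 and 30.3 in controls 1 to 3 and -51.1, -33.9 and 13.2 in PEG 1 to 3, and control 1 scored below PEG 3 in both classes (exact two-sided permutation p = 0.2 in each class, n = 3 each). In the plane of both components a straight line parted the groups in each class, as it did for 3 of the 10 groupings of the libraries, the real one included. The sources used here give no batch that separates the libraries, so no split by batch could be made.

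**Figure D3:**
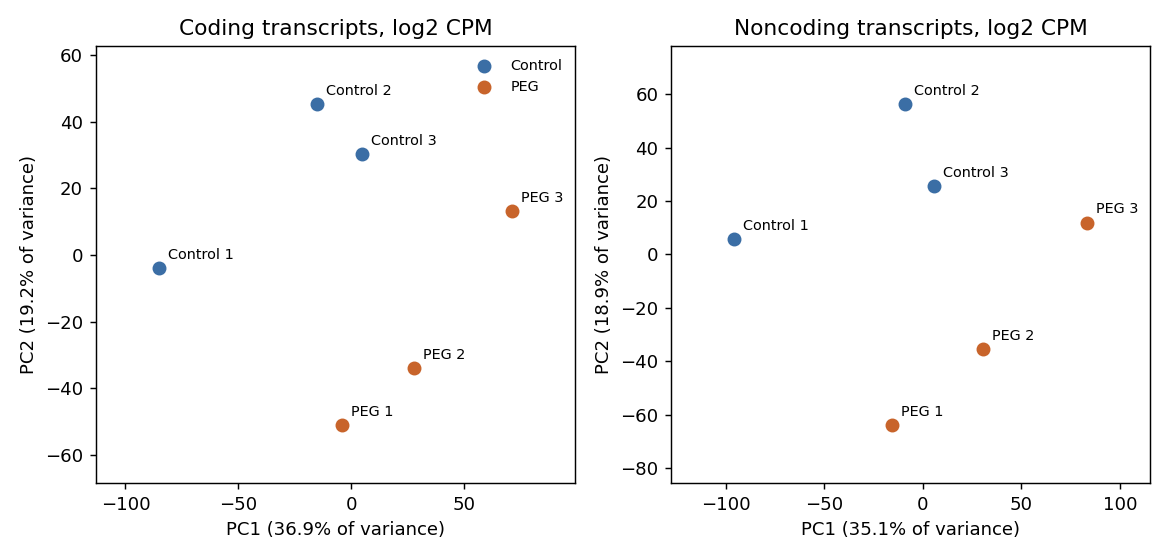
First and second principal components of log2 CPM for coding (left) and noncoding (right) transcripts, with 1 point per library, blue for control and orange for PEG. Control 1 and PEG 3 lie at the ends of the first component, which carries 36.9% of coding and 35.1% of noncoding variance, and PEG 1 lies to the left of control 3 in both panels.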

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

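Changes in scaling left the number of calls at 0 coding and 1 noncoding with RLE size factors or library totals. The log2 fold changes of the 4 transcripts described by identifier kept their sign under every alternative run. These were chosen from the same data and their groups did not overlap, so the sign could hardly turn and its stability is no test. DESeq2 called 378 coding and 61 noncoding transcripts, and 424 and 51 without its own filter on the transcripts tested by edgeR, a setting chosen after seeing the data. The replicate block gave 342 coding (167 higher, 175 lower) and 133 noncoding (93 higher, 40 lower) calls, and 3 and 8 beyond 2-fold. DESeq2 and the replicate block shared 167 coding and 44 noncoding calls. Same-numbered libraries deviated together with positive correlations of 0.299, 0.0495 and 0.273 for coding and 0.257, 0.0375 and 0.195 for noncoding transcripts, over 0.1 in 2 of 3 pairs. These values do not settle whether the numbers pair the libraries. The planned main fit without a block was kept, and its 0 coding and 1 noncoding calls depend on that choice. As a hint from the data, 5 of 6 libraries correlated best with their own number in each class, the exception being control 2. Leaving out 1 library gave 0 to 32 coding and 0 to 26 noncoding calls, and 0 to 16 and 0 to 18 beyond 2-fold, with each highest value without control 3. Testing both classes in 1 fit gave 1 coding and 0 noncoding calls. Without a filter, 16 noncoding transcripts were called and 4 beyond 2-fold. A filter of 1 CPM in 3 libraries, which kept more noncoding transcripts (55025) than the filter used, gave 5 and 1. At an adjusted p of 0.01 the noncoding count was 0. Of the other settings chosen after seeing the data, limma voom called 0 noncoding transcripts, and an adjusted p of 0.1 gave 13 coding and 2 noncoding calls and 1 of each class beyond 2-fold. Leaving out control 1 together with PEG 3 gave 0 coding and 6 noncoding calls. The difference in the noncoding share ranged from -0.215 to 0.12 percentage points without 1 library. That in the 100 most abundant coding transcripts ranged from -0.267 to 0.0903, and was 0.977 for the 1000 most abundant. The cause of these shifts was not tested. Counts summed per gene and gene lists gave no value, since the identifiers show no gene. Noncoding transcripts rested on few counts, with a median of 14 per library at a log2 CPM of 1 to 3.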

Other observations

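The tests of explanations for the transcripts of control 2 and for the axis of the libraries, and the counts over other splits, were chosen after the results they bear on were seen, while the edgeR test between groups and DESeq2 were planned.

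A few abundant transcripts varied widely between libraries. Of the 2262 tested coding transcripts with a mean of at least 100 CPM, 17 differed by at least 10-fold between the highest and the lowest library, as did 16 of 1160 noncoding transcripts. Within the controls or within the PEG libraries alone, 6 coding and 7 noncoding transcripts did so. The coding transcript Rep62478 stood at 4598, 4106 and 363.7 CPM in controls 1 to 3, and at 10880, 446.6 and 421.3 CPM in PEG 1 to 3, relative to coding totals. The noncoding transcript Rep88806 stood at 1262, 2338 and 4827 CPM in controls 1 to 3 and at 17570, 1269 and 2241 CPM in PEG 1 to 3, on the scale of noncoding totals. Neither passed the test between groups (edgeR adjusted p = 0.948 and 0.856).

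Control 2 held transcripts that were nearly absent elsewhere. In control 2, 371 transcripts had at least 20 counts while the other 5 libraries together had at most 1. The same criterion gave between 14 and 25 transcripts in each of the other libraries, and with at least 100 counts it gave 53 in control 2 and between 0 and 6 in the others. These 371 transcripts held 29285 counts, 0.0808% of the library, and at a minimum of 10 counts none of the 638 entered the tested sets. Greater depth is argued against, since the total of control 2 was 0.864 of the mean of the other libraries. A plant genotype that leaves the common transcripts without any count is argued against too. Only 10 transcripts with at least 20 counts in every other library were at 0 in control 2 (95% Poisson upper bound 18.4). In each other library, 1 to 8 were at 0. How shared reads were counted is unknown, so a genotype whose reads also count towards the common transcripts stays open. RNA of another organism in control 2 is a candidate explanation that stays open, since no sequence was at hand to name a source. Of its private transcripts with at least 20 counts, 78.4% were in the coding set, against 54.8% of the 93 private to the other libraries. Of all listed transcripts 31.4% were coding, but without a minimum count, and noncoding transcripts had lower counts. The share also moves with the cutoff. With at least 10 counts, 335 of the 638 in control 2 were coding, and each other library had 35 to 51 private transcripts, 9 to 16 of them coding. These shares do not decide the source.

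Libraries of both groups spread along a single axis from control 1 to PEG 3. The first component had a range of 89.8 among controls and 75.2 among PEG libraries, against a difference of 63.5 between group means, and control 1 and PEG 3 formed the ends in both transcript classes. Sequencing depth is argued against, since the deepest and the shallowest library lay 7.02% of the axis apart, and so is counting noise of rare transcripts as the whole cause, since the 10591 coding transcripts at 10 CPM or more gave an axis of their own with the same ends and 62.3% of their variance. It followed the axis of the 18199 below 10 CPM, with no transcript in common (over 6 libraries, Pearson r = 0.964, exact permutation p = 0.00972; Spearman rho = 0.829, exact permutation p = 0.0583), a relation that rests in part on control 1 and PEG 3 (r = 0.616 without them). The TMM factors of coding counts, unlike the totals, had their extremes at the same ends, 1.068 in control 1 and 0.9171 in PEG 3. In the other libraries they ran from 0.9932 to 1.011. Scores on the axis rose with the replicate number within both groups and in both classes. Coding scores were -85.0, -14.9 and 4.79 in controls 1 to 3, and -3.97, 27.9 and 71.2 in PEG 1 to 3. Each PEG library scored above the control of the same number. The sources used here do not say whether the number marks a shared batch, so a part tied to it stays open. A part due to PEG stays open too (exact two-sided permutation p = 0.2 on the coding axis, smallest possible 0.1), as do differences in seedling stage, organ proportions or RNA quality, which were not tested because the transcripts carry no names.

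The number of calls was set against all 10 splits of the 6 libraries 3 against 3, which are too few for a share under 0.05. In every other split, each group held 2 libraries of 1 condition and 1 of the other. Such a split keeps part of any PEG difference and adds to the spread within groups, so it gives no null level. With edgeR, the real grouping gave 118 coding transcripts with p below 0.001 and the highest other split 25, so that 1 of 10 splits gave as many. With p below 0.05 it gave 2624 and the highest other split 2344 (1 of 10). With DESeq2 it gave 378 coding calls and the highest other split 109, again 1 of 10. For noncoding transcripts the values were 78 against 62 with p below 0.001 (1 of 10), 2181 against 2452 with p below 0.05 (2 of 10) and 61 against 66 with DESeq2 (2 of 10). The split with 2452 and 66 parted controls 1 and 2 and PEG 1 from the rest, which follows the axis from control 1 to PEG 3. At an adjusted p below 0.05, edgeR gave 1 noncoding call against 2 in the highest other split (3 of 10), and 0 coding calls against 1. Beyond 2-fold it gave 0 against 1 in each class. A count of 0 is reached by every split (10 of 10) whatever the data, so the splits decide nothing where the real count was 0. DESeq2 called 8 to 109 coding transcripts in the other splits, which is not a count of false calls. It called 62 in simulated libraries without any change, and 67 of its 202 coding calls were false with 200 changed transcripts. These simulated libraries lack the differences that many transcripts share. Part of the 378 calls may be false, and how many cannot be told from these values.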
